A study of Arabidopsis thaliana with 6 samples.

How the data were processed

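Root RNA of 7-day-old Arabidopsis thaliana seedlings, grown on vertical plates, was measured on 6 Affymetrix ATH1 arrays, which carry several probes (a probe set) per transcript. There were 3 groups of 2 arrays: wild type, an RXR1 overexpressor and an rxr1 mutant. RXR1 (AT3G25240) encodes a DUF506 protein known as a repressor of root hair elongation. Groups and replicate numbers came from the labels. Nothing in the labels said that replicates came from separate plants or plates, so p-values measure only the spread between these arrays, which may be technical.

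The deposited values were RMA signals with the unit intensity, on a linear scale; RMA and Affymetrix Expression Console were named in the submitters' processing notes, with versions not given in the sources used here. The design had assumed log2 values, so log2 was taken before every test, with no pseudocount. Array medians ran from 108.3 to 111.3 intensity units. A second deposited table held the authors' correlation score (Pearson's r of linear signals) for each pair of arrays. A further deposited copy of the signals differed from the first by at most 5e-06. No detection calls were used here, and the number of arrays limits the precision.

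Of 22810 probe sets, 64 controls were left out and 22746 were tested. Gene names came from the platform annotation, updated through the TAIR10.1 gene table, which was used only for names and for which genes neighbour each other. It named 1 gene for 13513 probe sets, several for 503 and listed none for 8730; 13436 matched a locus, giving 13286 loci. A probe set without a single listed gene was left unnamed. Where 144 loci had more than 1 probe set, the brightest stood for the locus. The target RXR1 had 0 probe sets under its locus, so its level, which would check the labels, was not analysed here.

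Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per genotype, all 6 arrays, 3 residual and 4.25 prior degrees of freedom. The 3 contrasts were adjusted separately by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. All tests were two-sided.

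Before the data were examined, 32 gene lists were fixed, with 548 members. Only 68 members (12.4%) were measured under a name, 6 lists had none, and the 5 lists with at least 4 were tested. A further 31 lists, of which 30 had at least 4 measured members, were added once the gene table and a few rows of values had been seen but before any fit. They were adjusted as a separate family. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. The form with an estimated correlation gave larger p-values even where the estimate was negative. For the overexpressor against wild type, the unadjusted camera p of NPF transporters (estimate -0.0416) went from 0.00466 to 0.0592. That of beta-glucosidases (estimate -0.0189) went from 0.0025 to 0.0448. A call lost in this form therefore does not by itself show that correlated members made the call. Genes were named by a rule fixed before the data were examined. It took up to 10 called genes per direction and contrast with no overlap of the arrays, and filled the places to 5 with changes at unadjusted p under 0.01. It added list members and the genes that changed most in the same or in opposite directions in both lines.

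The fit was tested on simulated data with 200 changed probe sets among 22746, in 10 draws. For the overexpressor against wild type, 72.4% of 1.5-fold and 99.7% of 2-fold changes were recovered, and 7.49% of calls were unchanged probe sets, above the nominal rate. That simulation used the shrunken variances as they were, which vary too little. After its result had been seen, variances were also drawn around the shrunken estimates: 33.3% and 89.7% were then recovered, and 5.14% of calls were unchanged probe sets. For the mutant against wild type, 71.3% and 31.9% of 1.5-fold changes were recovered in the first and second version, with 7.59% and 3.83% of calls unchanged. For the overexpressor against the mutant, these were 73.1% and 32.2% recovered, with 7.03% and 5.49% of calls unchanged. Neither version gave wild type the wider spread it had here.

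The overlap of both lines and their counts against wild type at an unadjusted p were set against 50 simulations in which no group differed. The simulations kept the ratio of replicate spread between groups but not its absolute size, and were added after the observed values had been seen. They used the shrunken variances as they were, with probe sets varying independently. The test of dividing tissue between the overexpressor and the mutant had 3 forms, all written after the values had been seen. The first used the spread over genes and the second a limit on the spread between arrays chosen with the array values known; both of these 2 argued against the explanation. The form kept uses the interval from the spread between arrays and leaves it open.

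Alternatives were a replicate block, each array left out, the deposited copy, cyclic loess, median centring, filters on dim probe sets, an intensity trend, a robust prior, only the 4 arrays compared, array weights and other thresholds. Figures were drawn with matplotlib 3.10.9.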

Results

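The arrays compared roots that overexpressed RXR1 or carried an rxr1 mutation with wild-type roots, 2 arrays per genotype. RXR1 itself had no named probe set, so neither the overexpression nor the loss of its transcript was checked here. Wild-type replicate 2 stood apart: the authors' deposited correlations with the other 5 arrays ran from 0.97 to 0.9826, against 0.9938 to 0.9978 among the others. The replicate SD on the log2 scale was 0.191 in wild type, 0.101 in the overexpressor and 0.114 in the mutant. The 3' minus 5' difference of the actin control, a measure of RNA quality, was 1.39 and 1.40 log2 in the wild-type arrays and 1.11 to 1.29 in the other 4. That of ubiquitin went the other way (-0.104 and -0.0388 against -0.0266 to 0.0112). GAPDH's overlapped between them (0.373 and 0.28 against 0.148 to 0.357).

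The first comparison asked what RXR1 overexpression does to root transcripts. Genes of root hair growth were lower in the overexpressor, with adjusted p = 0.105 with an estimated correlation for the structural list and 0.36 for the wider one. XTH26, a xyloglucan-modifying enzyme of root hairs, fell by 1.34 ± 0.1 on the log2 scale (SE, n = 2 per group, adjusted p = 0.017). The class III peroxidase gene AT3G49960 fell by 1.31 ± 0.0895 (adjusted p = 0.017), and GH9C1, an endoglucanase of the root hair wall, fell by 0.84 ± 0.0877 (adjusted p = 0.0357). Among the named genes called, the largest fall was in AT5G24240, at -1.85 ± 0.158 (3.59-fold, adjusted p = 0.0224).

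Of 22746 probe sets, 23 were called, 0 higher and 23 lower, and 12 of these had 1 named gene. Further falls were found in AT1G19960 (-1.29), in the CAP-domain genes AT4G25790 (-1.23) and AT4G33730 (-1.07), and in AT1G05340 (-1.06). The peroxidase gene AT5G64120 (-1.03), the protease inhibitor gene AT2G38870 (-0.97) and the transporter gene OCT1 (-0.97) fell as well. AT1G34330 (-0.85) was called but lay outside the naming rule. At an unadjusted p under 0.05 there were 2695 probe sets, against 1137 by chance. In 50 simulations without any effect there were 1610 (1530 to 1699). There wild type kept its wider spread relative to the other groups, but not its absolute size. These simulations used variances that vary too little and drew probe sets independently, so their range may be too narrow. With only the 4 arrays compared there were 1978, and no simulation was run for that fit. No rise passed. Among named genes at an unadjusted p under 0.01 with no overlap of the arrays, the largest values were 1.01 ± 0.272 for AT4G39675 (adjusted p = 0.265; 0.67 without wild-type replicate 1) and 0.70 ± 0.148 for AT4G00780 (adjusted p = 0.19).

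**Figure D1:**
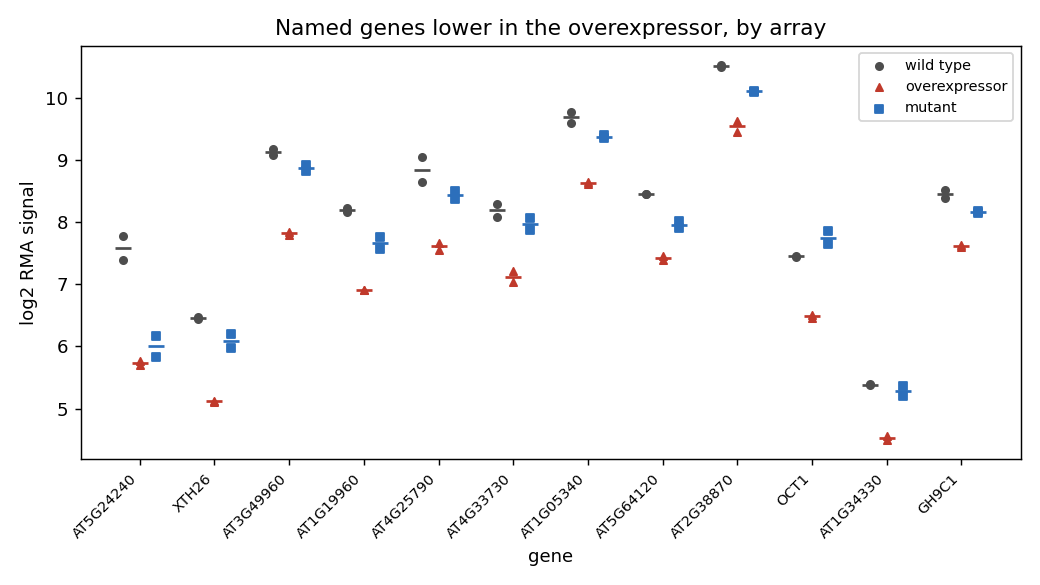
Log2 RMA signal (vertical axis) of the 12 named genes called lower in the overexpressor (horizontal axis), with 1 point per array and a bar at each genotype's mean. Both overexpressor arrays lie below both wild-type arrays for each of these genes.

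Of the 48 members of the root hair structural list, 6 (12.5%) were measured under a name. All 6 were lower, with a median of -0.74. Over all genes 1 was called, and 5 when adjusted over the list alone. EXPA7 and EXPA18, expansins of root hairs, were at -0.76 ± 0.0921 (adjusted p = 0.0526) and -0.72 ± 0.128 (adjusted p = 0.127). The list was called by camera (adjusted p = 6.2e-09), with adjusted p = 0.105 with an estimated correlation and 0.0104 with fry. The wider root hair list, added later, had 25 of 71 members measured (35.2%). It shares XTH26 with the structural list, so their results are not separate. In the wider list 25 of 25 members were lower (median -0.60), 4 were called over all genes and 20 adjusted over the list alone. Its camera adjusted p was 2.86e-25, and adjusted p = 0.36 with an estimated correlation. Against the mean of the other 5 arrays, this list's median was 0.21 in wild-type replicate 1, 0.375 in wild-type replicate 2, and -0.54 and -0.39 in the overexpressor arrays.

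**Figure D2:**
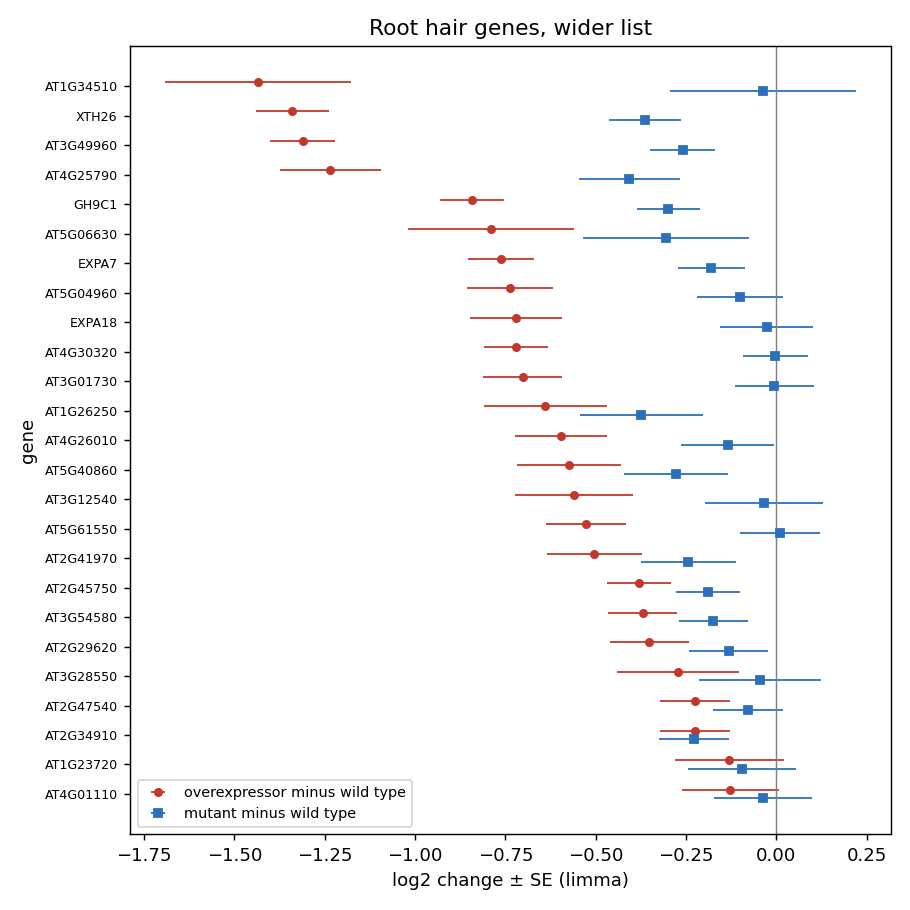
Log2 change against wild type with its limma SE (horizontal axis) for the 25 measured genes of the wider root hair list (vertical axis), in the overexpressor (circles) and the mutant (squares). All 25 overexpressor values lie below 0, with a median of -0.60, against -0.135 in the mutant.

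Among the other added lists, camera called 5 lower and 2 higher. Photosystem and thylakoid genes were lower in 10 of 13 (median -0.35, 0 called, 6 adjusted over the list alone), with PSAN at -0.72 ± 0.112 (adjusted p = 0.0895). Their camera adjusted p was 0.000823, and adjusted p = 0.528 with an estimated correlation. Lower too were UDP-glycosyltransferases (median -0.07), beta-glucosidases (-0.10), NPF transporters (-0.15) and xyloglucan transglycosylases (-0.12), each with adjusted p = 0.36 with an estimated correlation. The only called member of the xyloglucan list was XTH26, which is also in both root hair lists, so this result is not separate from theirs. Chloroplast-encoded genes were higher in 59 of 69 (median 0.155) and histones in 6 of 7 (median 0.26), each with adjusted p = 0.528 with an estimated correlation. Without wild-type replicate 2 the histone median was 0.12. The remaining added lists had adjusted p from 0.0721 to 0.974. The DUF506 family (median -0.29, adjusted p = 0.184), iron deficiency (-0.19, 0.184), auxin response (-0.06, 0.486) and cell wall (0.09, 0.773) lists were not called.

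Leaving out either overexpressor array or either mutant array ended all 23 calls (0 called), although all 23 probe sets kept their direction. A mutant array left out cannot move these differences, only their variance and degrees of freedom, and the 23 then had adjusted p up to 0.16. Without wild-type replicate 1 the only control left was wild-type replicate 2, which stood apart, so the calls of that fit rest on that array.

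The second comparison asked what the rxr1 mutation does. Of 22746 probe sets 1 was called, for SGP1 (AT5G54840), which encodes a small GTP-binding protein and fell by 4.33 ± 0.258 on the log2 scale in the mutant (n = 2 per group, adjusted p = 0.0104). Its log2 signal was 5.34 and 4.66 in the mutant arrays, 9.02 and 9.64 in wild type, and 9.18 and 9.03 in the overexpressor. The mutant signals were not shown to lie above background, so this fall is a lower bound if the transcript was absent there. Early stress-responsive genes were lower in 21 of 21 measured members, with 0 called over all genes and camera adjusted p = 0.477 with an estimated correlation. Genes of this kind are induced within minutes by touch, wounding and handling. Whether handling differed between the groups was not tested, so this is not shown to be an effect of the mutation. At an unadjusted p under 0.05 there were 2122 probe sets, against 1137 by chance and 1780 (1680 to 1865) in the same simulations, which carry the same limits. With only the 4 arrays compared there were 1346, and no simulation was run for that fit.

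**Figure D3:**
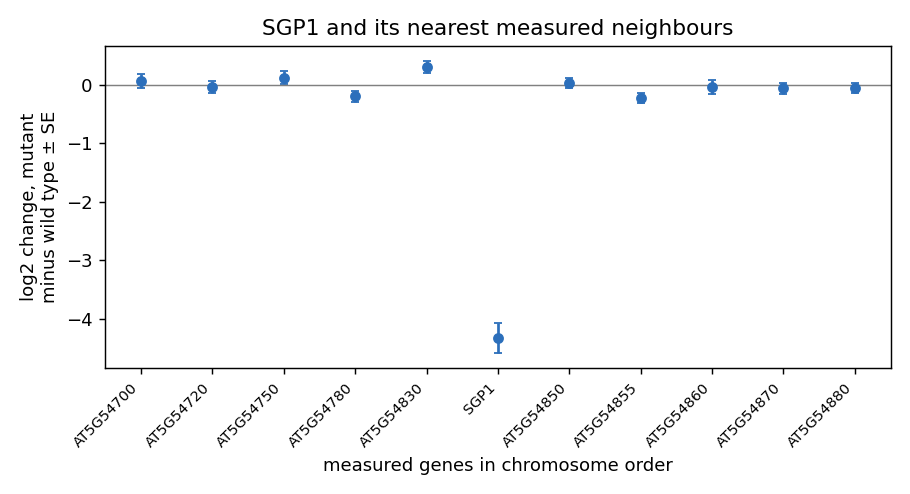
Log2 change in the mutant against wild type with its limma SE (vertical axis) for SGP1 and the 5 nearest measured genes on each side, in chromosome order (horizontal axis). SGP1 lies at -4.33, and the neighbours lie between -0.23 and 0.31.

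Among changes that did not pass, AT5G24240 was at -1.58 ± 0.158 (adjusted p = 0.198), and AT2G25735 and AT4G27654 at -1.45 ± 0.338 and -1.39 ± 0.314 (both adjusted p = 0.524). Among named genes at an unadjusted p under 0.01 with no overlap, the largest positive values were 1.21 ± 0.341 for AT1G52070, 0.98 ± 0.207 for AT5G51520 and 0.90 ± 0.106 for AT5G35940. Without wild-type replicate 2, which stood apart, the first of these was 0.66 and the second 0.62. The rapid stress list, added later, had a median of -0.38, with 0 members called over all genes and 9 adjusted over the list alone. STZ, a zinc-finger repressor induced by stress, was at -1.18 ± 0.426, but at -0.42 without mutant replicate 1 and -1.94 without mutant replicate 2. This list's camera adjusted p was 2.76e-12, and adjusted p = 0.477 with an estimated correlation.

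The DUF506 family, to which RXR1 belongs, was lower in 6 of 6 measured members (median -0.40, 0 called, 1 adjusted over the list alone), led by AT2G39650 at -0.53 ± 0.123. Camera called it (adjusted p = 0.000787), with adjusted p = 0.29 with an estimated correlation. The root hair structural list was not called (median -0.09, adjusted p = 0.102), nor were iron deficiency (0.0812), auxin response (0.707) and cell wall (0.748). The wider root hair list was lower in 24 of 25 (median -0.135, 0 called, camera adjusted p = 0.000155), with adjusted p = 0.521 with an estimated correlation. Without wild-type replicate 2 its median was -0.07 and its camera adjusted p 0.553.

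Camera also called NPF transporters (median -0.17, 11 of 11 lower), xyloglucan transglycosylases (-0.22), UDP-glycosyltransferases (-0.07) and SWEET sugar transporters (-0.15) lower, each with adjusted p = 0.477 with an estimated correlation. Photosystem genes (-0.18) were called lower, and histones (0.18) and chloroplast-encoded genes (0.10) higher, each with adjusted p = 0.521 with an estimated correlation. Without wild-type replicate 2 the histone median was 0.06. The remaining added lists had adjusted p from 0.0844 to 0.95. The SGP1 call was lost (0 called) without either overexpressor array, where the change stayed at -4.33 (adjusted p = 0.142), since only the variance and degrees of freedom differed. It was lost too without mutant replicate 2, at -3.99 (adjusted p = 0.0785). Without wild-type replicate 1 the only control left was again wild-type replicate 2.

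The third comparison set the overexpressor against the mutant directly, so that no wild-type mean entered the difference. AT3G49960 was lower in the overexpressor by -1.05 ± 0.0895 (adjusted p = 0.042) and OCT1 by -1.26 ± 0.0988 (adjusted p = 0.0356). SGP1 was higher by 4.11 ± 0.258 (17.2-fold, adjusted p = 0.0151), with the same limit at the mutant's dim signal. Root hair genes were lower as lists, with adjusted p = 0.0659 with an estimated correlation (structural) and 0.384 (wider). Early stress-responsive genes were higher as a list, with camera adjusted p = 0.384 with an estimated correlation and 0 members called. The same limit on handling applies here.

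These 3 were the only probe sets called, 1 higher and 2 lower; with each array centred on its median, 1 was called, 1 higher and 0 lower. At an unadjusted p under 0.05 there were 1148, against 1137 by chance. The variance behind these p-values included the wider wild-type spread, so the 1148 does not show that the lines were alike. With only the 4 arrays compared there were 2394. No simulated count without any effect was made for this comparison. The root hair structural list was lower in 6 of 6 (median -0.64, 0 called, 5 adjusted over the list alone, camera adjusted p = 3.2e-12), with adjusted p = 0.0659 with an estimated correlation and 0.0191 with fry. AT1G34510, a peroxidase gene of this list, was at -1.40 ± 0.257 and XTH26 at -0.97 ± 0.1 (adjusted p = 0.275 and 0.0917). The wider root hair list was lower in 24 of 25 (median -0.48, 1 called, 13 adjusted over the list alone, camera adjusted p = 4.59e-27), with adjusted p = 0.384 with an estimated correlation.

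The rapid stress list was higher in 19 of 21 (median 0.41, 0 called, 8 adjusted over the list alone, camera adjusted p = 3.6e-13), with adjusted p = 0.384 with an estimated correlation. STZ was at 1.72 ± 0.426, AT4G29780 at 1.71 ± 0.422 and the calmodulin-like gene CML38 at 1.55 ± 0.318, none of which passed. Without mutant replicate 1 STZ was at 0.95, and without overexpressor replicate 2 AT4G29780 was at 1.08. The DUF506 family was called higher (median 0.08, 6 of 6, adjusted p = 0.0239), with adjusted p = 0.385 with an estimated correlation. Late embryogenesis abundant genes (median -0.15), beta-glucosidases (-0.07) and glutathione transferases (-0.13) were called lower, each with adjusted p = 0.384 with an estimated correlation. Chloroplast-encoded genes were called higher (median 0.07), with adjusted p = 0.869 with an estimated correlation. The remaining added lists had adjusted p from 0.0525 to 0.929. The iron deficiency (0.754), auxin response (0.754) and cell wall (0.697) lists were not called. Leaving out any overexpressor or mutant array ended the calls of AT3G49960 and OCT1. Without either overexpressor array, or without mutant replicate 2, 0 probe sets were called, with SGP1 at 4.03, 4.19 and 3.77; without either wild-type array there were 58.

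Last, the changes of both lines against wild type were set side by side. Of the 23 probe sets called in the overexpressor, 22 were also lower in the mutant, with a median of -0.31 there against -1.03 in the overexpressor. The 23 were picked for their falls in the overexpressor, which enlarges the -1.03, so these medians do not compare the lines fairly. Both lines were compared with the same wild-type arrays: in 50 simulations without any effect, 22 to 23 of the 23 strongest falls in one line were also lower in the other, so this agreement does not by itself show a shared change. AT5G24240 was at -1.85 in the overexpressor and -1.58 in the mutant. STZ, CML38, AT3G10930 and AT4G27280 had positive values in the overexpressor (0.54, 0.50, 0.47 and 0.54) and negative ones in the mutant (-1.18, -1.06, -1.04 and -0.61), and AT4G37220 the opposite (-0.58 and 0.67). None of these values passed, and single arrays moved them: in the mutant, AT3G10930 was at -0.31 without replicate 1 and AT4G37220 at 0.18 without replicate 2. In the overexpressor CML38 was at 0.06 without replicate 2.

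Across 22746 probe sets, which are not independent replicates, the changes correlated at r = 0.669. Both used the same wild-type arrays, and 100 simulations without any effect gave 0.759 (0.747 to 0.769), above the observed value. The covariance was 0.0241 against a simulated 0.0135, a difference of 0.0106. These 100 simulations were scaled from the shrunken variances, not to the observed wild-type SD of 0.191. Their shared wild-type part may therefore be too small and the 0.0106 too large. At an unadjusted p under 0.05, 615 probe sets were higher in both and 417 lower in both, against 60.9 and 63.9 for independent lists. Simulated groups without any effect, sharing the wild-type arrays, gave 388 higher in both (345 to 433) and 393 lower in both (335 to 439). The simulated probe sets varied independently, which real ones do not. The control was not split, since each part would hold 1 array. In these simulations the shared controls alone gave most of the excess over independent lists. The 417 lower in both lay within the simulated range, and the 615 higher in both lay above it. Wild-type replicate 2, which stood apart, enters both changes, and independent draws cannot reproduce genes that deviate together in 1 array. The 615 therefore does not by itself show a shared rise.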

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

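The counts of calls depended strongly on single arrays, and the cause was not tested except where the construction of the fit settles it. Leaving out each array in turn gave 0 to 3790 calls for the overexpressor, 0 to 2743 for the mutant and 0 to 58 between them. An array left out can leave a lone sample that is assumed to vary like the other groups. Without either wild-type array the variance came from the overexpressor and mutant arrays alone. Those fits therefore differed only in which wild-type array was the lone control. For each line against wild type the highest count came without wild-type replicate 1, where that control was wild-type replicate 2, which stood apart. For the overexpressor (23 calls), there were 6 over the probe sets brighter than the median, 38 with an intensity trend, 36 with a trend and robust prior, 0 with only the 4 arrays compared and 12 with array weights. Other thresholds gave 12 (adjusted p and 2-fold), 37 (2-fold, no overlap, no p) and 97 (adjusted p under 0.1). Chance alone gives no overlap for 33.3% of probe sets. For the mutant (1 call), the 4 arrays alone gave 0 and 2-fold with no overlap 30. Between the lines (3 calls), median centring gave 1, the 4 arrays alone 58, array weights 100, 2-fold with no overlap 43 and adjusted p under 0.1 gave 5. The deposited copy of the values and cyclic loess kept all 3 counts within 1.5 times.

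The replicate block gave 167, 2 and 30 probe sets in the 3 comparisons. The deviations of same-numbered arrays correlated at 0.0533, 0.316 and 0.125. By the rule used, every pair had to exceed 0.1, and 1 did not, so the numbers were not treated as pairing the arrays; a shared factor is not excluded.

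For lists fixed beforehand, an estimated correlation gave 0 calls in each comparison. In the mutant, fry gave 0, the replicate block 2 and cyclic loess 3, and between the lines fry gave 1. Leaving out arrays gave 1 to 1, 1 to 3 and 1 to 2 lists. The added lists, and all their alternatives, were chosen after seeing the gene table. They gave 0 calls with an estimated correlation or fry in each comparison, and 5 for each line against wild type over the brighter probe sets. Leaving out arrays gave 4 to 11, 4 to 10 and 3 to 6. The correlation of the changes ran from 0.57 to 0.845 with arrays left out, highest without wild-type replicate 1.

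Among named genes 4 values reversed, each without 1 wild-type array. In the overexpressor, AT1G26390 ran from -2.09 (without wild-type replicate 2) to 0.046 (without replicate 1), AT1G09310 from -2.31 to 0.35, and AT1G50060 from -0.026 to 1.76. In the mutant, AT1G09310 ran from -2.54 to 0.12. None of these had been called. The alternatives planned for RXR1 were not run, since it had no named probe set. Without detection calls, dim probe sets could not be set against background.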

Other observations

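The tests of explanations in this part were all chosen after the results had been seen. Some single members of other lists stood out when adjusted over the list alone. BHLH101, a transcription factor of the iron deficiency response, was at -0.71 ± 0.169 in the overexpressor (limma, adjusted p = 0.0224 over the list alone) and -0.63 ± 0.169 in the mutant (0.0411). BGLU45, a beta-glucosidase of lignin precursors, was at -1.11 ± 0.179 in the overexpressor (0.00844), and LEA4-5 at -0.73 ± 0.114 (0.00156). None of these 3 passed over all genes.

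Root hair genes were lower in the overexpressor, although the list calls were lost with an estimated correlation (adjusted p = 0.105 and 0.36). Calls were lost in this form even for lists with a negative estimate, such as NPF transporters (-0.0416). The loss therefore does not by itself show that correlated members made the root hair calls. Wild-type replicate 2 as the sole cause is argued against, since the wider list's median without it was -0.474, 79.6% of its value with all arrays. More dividing root tip tissue than in wild type stays open. Histones and cell division genes were at 0.252 in the overexpressor and 0.22 in the mutant, but the 0.252 was 0.0561 without wild-type replicate 2. The root hair list was at -0.60 and -0.135, so it differed between the lines where histones and cell division genes were nearly equal. More dividing tissue than in the mutant stays open too, since the array medians differed by 0.0049 with an interval from -0.137 to 0.146. The 0.0049 gives no sign of more in the overexpressor, but the interval does not exclude it. Lower root hair gene activity under RXR1 overexpression and an effect of this transgenic line were not tested, and no measurement of hairs was used here.

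Wild-type replicate 2 stood apart from the other arrays. RNA degradation is argued against, since only 1 of 3 control transcripts had its highest 3' minus 5' difference there. Over both wild-type arrays actin's difference was higher (1.39 and 1.40 against 1.11 to 1.29) but ubiquitin's was lower (-0.104 and -0.0388 against -0.0266 to 0.0112), so a difference in RNA quality with genotype is not excluded for the changes against wild type. More green tissue in that array alone is argued against too, since photosystem genes lay at 0.188 in it and at 0.26 in wild-type replicate 1. Both values lay above those of the overexpressor and mutant arrays (-0.233 to 0.0455), although chloroplast-encoded genes were higher in both lines. More green tissue in wild type is therefore not excluded for the changes against wild type. Less dividing root tip tissue in the harvested material may account for part of the difference: histones and cell division genes lay at -0.433 there, against -0.00922 to 0.128 in the other arrays.

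SGP1 was lower in the mutant. A deletion reaching the neighbouring genes is argued against only if those genes are expressed in these roots. The nearest measured neighbours were at 0.0281 and 0.31, but were not shown to lie above background. A single deviating mutant array is argued against by a log2 gap of 3.68 between the groups, with the mutant arrays 0.68 apart. A mutant from another strain, whose sequence the probes miss, is argued against by 0 other probe sets lying 4-fold lower in both mutant arrays. A lesion within SGP1 carried by this line, a sequence difference under its probes alone, and regulation by RXR1 stay open and were not tested.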
